A study of Oryza sativa with 6 samples.

How the data were processed

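Poly(A) RNA from leaves of 4-week-old rice was sequenced in 6 libraries, 2 each of nontransgenic plants (WT), plants overexpressing MIR171f (OX) and CRISPR-Cas9 mutants of MIR171f (KO). Per the labels' protocols, seeds germinated for 3 days at 28 °C on Murashige and Skoog medium, seedlings grew in soil pots in a greenhouse, RNA was extracted with the RNeasy Plant Mini Kit and libraries were made with the TruSeq stranded mRNA kit. The build is IRGSP-1.0 per the submitters' processing notes. The aligner, the counter, whether reads were counted by strand, the authors' statistical test and their enrichment tool are not given in the sources used here. Where reads were counted without strand, overlapping and antisense transcripts cannot be told apart, and near-identical gene copies and transcripts of 1 gene may share reads.

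The deposited table is a selection made by the authors. All 7194 transcripts (6535 genes on 12 chromosomes, 7058 protein-coding and 136 noncoding transcripts) had, per the file headers and as tested on the values, a fold change of at least 2 and an unadjusted p below 0.05 in at least 1 of the authors' 3 comparisons. A total of 573 genes had more than 1 listed transcript. The ratio of the authors' adjusted to unadjusted p-values shows that the authors tested 27384 transcripts. The deposited estimated counts per transcript are whole numbers of at least 1. In 100.0% of values they equal, within a tolerance of 0.02 below and 1.02 above, the authors' deposited FPKM converted back to reads and rounded up. FPKM values, per the file headers, are scaled by the authors to transcript length and library depth. The deposited TPM values are scaled by the authors over all transcripts, including those not listed, and were not tested. The authors' log2 normalised values equal log2 of the count over an effective library total plus 1, and the effective totals were recovered from them. The authors' deposited fold changes are linear and signed, a fall by n being written as −n. The authors' deposited p-values are unadjusted and Benjamini-Hochberg adjusted.

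The totals of all reads, recovered from FPKM and counts, were 31969823 and 30005810 (WT), 30315912 and 33404964 (OX), and 28374222 and 29840153 (KO). Listed transcripts held 30.5% and 31.0% of them in WT, 24.3% and 24.5% in OX, and 29.8% and 29.5% in KO. The authors' effective totals divided by these give scaling factors of 0.808 and 0.796 for WT, 1.05 and 1.024 for OX, and 0.919 and 0.917 for KO. Plain library totals in place of effective totals shift every log2 ratio by 0.37 for OX against WT, 0.195 for KO against WT and 0.174 for OX against KO.

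Counts were tested with edgeR 4.0.16 (quasi-likelihood test with robust dispersion, R 4.3.3) on 1 fit of all 6 libraries with group as the only term. The authors' effective totals served as library sizes, because normalisation factors computed on transcripts selected for change are unreliable. The filter filterByExpr kept 7034 transcripts and removed 160. P-values were adjusted by Benjamini-Hochberg over the 27384 transcripts that the authors tested, counting each transcript outside the table as having a larger p, and a transcript with an adjusted p below 0.05 is called. The SE of a log2 fold change is its size divided by the square root of the F statistic. The common dispersion was 0.0847, a biological coefficient of variation of 0.291. Libraries of a group differed by more than sampling noise, with chi-square per degree of freedom of 16.6 (WT), 18.9 (OX) and 13.6 (KO). Within WT and KO, repeat preparations of 1 RNA could also show this. Each library was used as 1 replicate as the labels number them.

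The procedure was tested on simulated data with the transcripts' own means and library sizes. In 6 simulated data sets of OX against WT with 7034 transcripts each, calls were made for 7.67% of 300 transcripts raised 2-fold (4% to 12% per data set) and 43.7% of 300 raised 4-fold (36% to 56%). They were made for 5.67% of 300 transcripts lowered 2-fold (2% to 10%) and 28.3% of 300 lowered 4-fold (16% to 42%). Of 40515 tests of unchanged transcripts 13 were called. In the same data sets 1 of 41703 tests of KO against WT, where nothing was changed, was called, and 4.6% had an unadjusted p below 0.05. The simulated spread was each transcript's estimated dispersion, so these shares average over differing spreads. In the deposited data some transcripts were called at less than 2-fold.

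The design, the alternatives, the rule for named genes and 19 gene lists were fixed before the data were examined. The lists, matched to the file's descriptions, were miR171 targets, miR171 precursors, flavonoid, phenylpropanoid and lignin, photosynthesis, drought and LEA, abscisic acid, heat shock, redox, jasmonate, diterpenoid phytoalexin, defence proteins, circadian clock, nutrient, dividing cells, meristem and young leaf base, secondary wall and vasculature, root, and pollen or anther. No description matched a precursor. The 5 entries that matched only as part of another word were removed. Since the table is a selection, the design put counts of called members and Fisher's exact test (two-sided) in place of the planned set test. Fisher's test set a list's higher and lower calls against those of the other listed transcripts, adjusted by Benjamini-Hochberg over a comparison's lists. It takes transcripts as independent, even those of the same gene, so its p does not measure replication between plants. Counts adjusted over the list alone use only the members' p-values.

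Genes are named by the description that the file pairs with each ID. Named genes are the listed targets, all flavonoid members, the 10 largest rises and 10 largest falls of each comparison among called transcripts with a mean count of at least 20, with both libraries of 1 group beyond both of the other and with a description that says more than hypothetical, up to 4 members with the smallest p of every other list, and the 5 transcripts with the smallest larger p among those called in both comparisons with WT, for the same and for opposite signs. The report names a part of them. Transcript 03 of Os02g0830100, transcripts of Os06g0199200 and Os05g0592800 outside that rule, and genes in the closing part that the rule does not reach, were chosen after their values were seen.

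For the shared WT libraries, 20 draws of unchanged OX and KO groups were simulated. Log2 ratios of single OX and KO libraries to different WT libraries were compared over the 6254 tested transcripts with a mean count of at least 20. Alternatives were DESeq2 1.42.0 size factors, plain library totals, the DESeq2 Wald test, no filter or a minimum of 10 counts, only the 2 groups compared, the replicate number as a block, an additional 2-fold threshold, other thresholds for the overlap, and leaving out each library. TMM recomputed on the listed transcripts, adjustment over the listed transcripts only, 1 transcript per gene and the authors' adjusted p were added after seeing the data, as were plain library totals for the overlap, lists and named genes, and DESeq2 calls for the lists. Where a group was left with 1 library, that library was assumed to vary like the other groups. Tables were joined and Fisher's tests run in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, limma 3.58.1 was loaded with edgeR, and plots were drawn with matplotlib 3.10.9. The authors' transcript-level enrichment table, which repeats terms and values of the other tables, was not used.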

Results

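Leaf messenger RNA of 4-week-old rice was sequenced from 3 genotypes with 2 libraries each: transgenic plants overexpressing MIR171f, a gene that encodes a miR171 microRNA (OX), CRISPR-Cas9 mutants of that gene (KO), and nontransgenic controls (WT). MicroRNAs of the miR171 family guide the cleavage of transcripts for Scarecrow-like proteins, which are transcription factors of the GRAS family. By its title the study links miR171f and its SCL6-type targets to drought tolerance and flavonoid genes. The OX libraries came from 2 transgenic lines, and both KO libraries carry line number 2. The labels do not say whether the WT libraries, or the KO libraries, were separate plants, so p-values measure only the spread between these samples, which within WT and KO may be technical.

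The expression table holds 7194 transcripts of 6535 genes. Each of them differed at least 2-fold with an unadjusted p below 0.05 in at least 1 of the authors' 3 comparisons, so every number of changed transcripts given here is a number among the authors' selected transcripts. Listed read counts summed to 9739821 and 9294810 in the WT libraries, 7376228 and 8192874 in the OX libraries, and 8452027 and 8802235 in the KO libraries. The authors' effective library totals were 25823009 and 23869522 for WT, 31743854 and 34214364 for OX, and 26078166 and 27349913 for KO. Expression levels are CPM, counts scaled to these effective totals, given as mean ± SD with n = 2 libraries, and fold changes are on the log2 scale with their standard errors (SE). For gene lists, pairs of numbers under the other scalings are higher and lower calls, adjusted over all transcripts, with DESeq2 size factors, with TMM computed on the listed transcripts and with plain library totals, in that order. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Across listed transcripts, log2 CPM of the 2 libraries of a group correlated with Pearson's r of 0.972 (WT), 0.978 (OX) and 0.977 (KO), where transcripts are not independent replicates. Coordinates are transcript spans on IRGSP-1.0, and exons and untranslated regions are not given in the table.

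No MIR171 precursor was found among the listed descriptions, so the modified gene gave no check of the labels. Only the 3 listed Scarecrow-like targets could be tested, and all 3 fell in OX. Os02g0662700, described as similar to Scl1 (chromosome 2, 26841588 to 26844306), stood at 63.6 ± 4.24 CPM in WT, 32.8 ± 2.38 in OX and 68.2 ± 1.28 in KO. It fell in OX against WT (log2 fold change -0.95, SE 0.08, adjusted p = 0.00163) and was not called in KO against WT (0.10, SE 0.08, adjusted p = 1). Os06g0105350, similar to Scarecrow-like 6 (chromosome 6, 365289 to 366758), fell in OX (-1.92, SE 0.19, adjusted p = 0.00249) and also in KO (-1.75, SE 0.19, adjusted p = 0.00401), from 23.5 ± 1.99 CPM in WT to 6.20 ± 1.022 and 6.98 ± 1.14. Os10g0551200, also similar to Scl1 (chromosome 10, 21635191 to 21637744), fell from 12.4 ± 0.777 CPM to 6.60 ± 1.13 in OX (-0.91, SE 0.16, adjusted p = 0.0199) and stood at 14.8 ± 0.392 in KO. Its OX call was lost under other settings (adjusted p 0.0985 with plain library totals, 0.0604 without WT 1, 0.0925 without WT 2, 0.0839 without OX 1, 0.0556 without KO 1, 0.0562 without KO 2). Between OX and KO, Os02g0662700 was lower in OX (-1.06, SE 0.08, adjusted p = 0.00130), as was Os10g0551200 (-1.16, SE 0.16, adjusted p = 0.00958, with adjusted p 0.0670 without KO 1, 0.0603 without KO 2), whereas Os06g0105350 was not called (-0.17, SE 0.19, adjusted p = 1). The target list gave 3 lower calls in OX against WT, 1 in KO against WT and 2 in OX against KO (1 without KO 1 or KO 2), with the same numbers adjusted over the list alone. Its split between higher and lower calls did not differ from that of the other listed transcripts (Fisher's exact test, two-sided, adjusted p = 0.229, 0.676 and 0.859). Because the title names SCL6 targets, this list is not independent evidence of its direction.

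**Figure D1:**
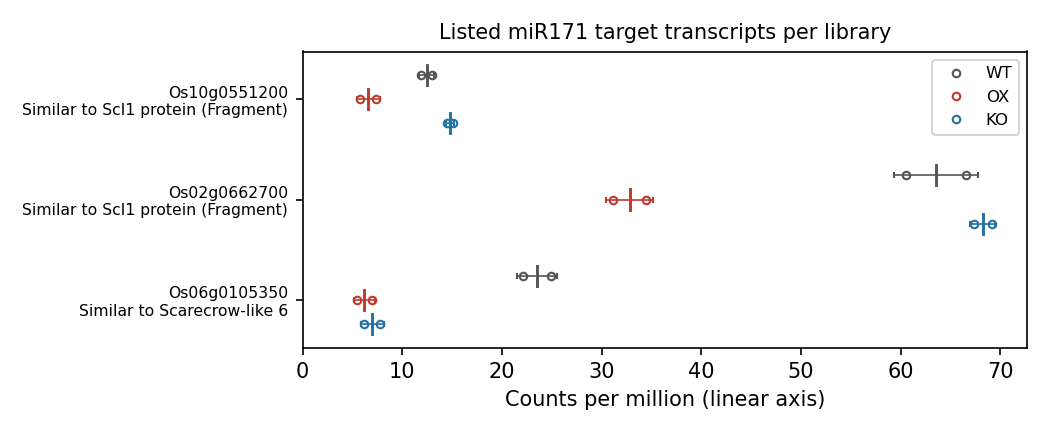
Expression of the 3 listed Scarecrow-like targets of miR171 in each library, in CPM of the authors' effective totals on a linear axis. Os02g0662700 averages 32.8 CPM in OX against 63.6 in WT, and Os06g0105350 lies below WT in all 4 OX and KO libraries.

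Overexpression of MIR171f was compared with WT to ask what the microRNA gene changes when it is raised. A starch-synthesis enzyme, a terpene synthase and a lipoxygenase had some of the largest rises. Os05g0580000, an ADP-glucose pyrophosphorylase of starch synthesis (chromosome 5, 28871794 to 28877277), rose from 3.08 ± 0.682 to 402 ± 3.05 CPM (log2 fold change 7.02, SE 0.17, adjusted p = 6.06e-05). A sesquiterpene synthase transcript, Os08g0167800 (chromosome 8, 3961276 to 3965426), rose from 11.7 ± 0.310 to 1065 ± 34.3 CPM (6.50, SE 0.06, adjusted p = 6.50e-06). The lipoxygenase Os12g0559200 (chromosome 12, 22854749 to 22860198), from a family that starts oxylipin and jasmonate synthesis, rose from 81.1 ± 17.3 to 2297 ± 77.8 CPM (4.82, SE 0.18, adjusted p = 2.10e-04). Rises above 6 on the log2 scale were also found for the transferase family gene Os12g0458100 (6.67, SE 0.13, adjusted p = 3.76e-05), and for the carboxyl methyltransferase Os02g0719600 (6.23, SE 0.36, adjusted p = 4.01e-04).

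A florigen-like transcript and MADS-domain genes had some of the largest falls in OX. Os06g0157700, similar to SP3D, the florigen of tomato (chromosome 6, 2940004 to 2942452), fell from 41.7 ± 2.18 CPM in WT to 0.479 ± 0.232 in OX (log2 fold change -6.42, SE 0.32, adjusted p = 3.09e-04). The MADS-domain gene Os03g0215400 (chromosome 3, 6052902 to 6061365) fell from 17.3 ± 0.489 to 0.184 ± 0.0955 CPM (-6.53, SE 0.32, adjusted p = 2.47e-04), and Os03g0752800, similar to MADS-box transcription factor 14, fell from 11.4 ± 0.221 to 0.663 ± 0.136 CPM (-4.09, SE 0.23, adjusted p = 3.57e-04). A glutaredoxin C1 transcript, Os01g0368900, fell from 139 ± 2.16 to 2.14 ± 0.0919 CPM (-6.02, SE 0.07, adjusted p = 1.74e-05). Nicotianamine synthase 3, Os07g0689600, an enzyme that makes a metal chelator, fell from 71.3 ± 5.30 to 1.61 ± 0.257 CPM (-5.46, SE 0.14, adjusted p = 5.80e-05). For Os06g0199200, a gene with a Smr domain, transcript 01 fell (-6.47, SE 0.63, adjusted p = 0.00348) while transcript 04 of the same gene rose (1.95, SE 0.08, adjusted p = 1.62e-04), and its 3 listed transcripts together held 202 ± 5.15 CPM in WT and 186.0 ± 2.53 in OX.

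Of the flavonoid transcripts, the pathway in the study's title, more were called higher than lower in OX. Of 16 listed members, 9 rose, 1 fell and 6 were not called, with 10 higher and 2 lower adjusted over the list alone. The splits were 8 and 2, 9 and 1, and 10 and 1 under the other scalings. The list is not independent evidence of its direction, since the title names the pathway, and its split did not differ from that of other listed transcripts (Fisher's exact test, two-sided, adjusted p = 0.215). Chalcone synthase Os11g0530600, which catalyses the first committed step (chromosome 11, 19277597 to 19281006), rose from 2.85 ± 0.528 to 28.5 ± 3.06 CPM (log2 fold change 3.32, SE 0.22, adjusted p = 6.32e-04). The chalcone isomerase domain genes Os12g0115700 (3.56, SE 0.29, adjusted p = 0.00121), Os06g0203600 (2.75, SE 0.11, adjusted p = 1.41e-04) and Os11g0116300 (2.16, SE 0.19, adjusted p = 0.00161) rose as well. Leucoanthocyanidin dioxygenase, which makes anthocyanidins, rose for Os09g0354300 from 0.263 ± 0.0431 to 4.66 ± 0.182 CPM (4.13, SE 0.38, adjusted p = 0.00182) and for Os03g0289800 from 0.547 ± 0.116 to 6.16 ± 0.241 CPM (3.49, SE 0.27, adjusted p = 9.93e-04). A flavonoid 3'-monooxygenase, Os10g0320100 (2.57, SE 0.28, adjusted p = 0.00331), and a flavanone 3-hydroxylase-like gene, Os03g0122300 (2.02, SE 0.22, adjusted p = 0.00367), were also higher. The ninth rise, the dioxygenase Os06g0178650 (0.68, SE 0.14, adjusted p = 0.0331), was lost with DESeq2 size factors, with the replicate block and when any 1 library was left out (adjusted p 0.10 with DESeq2 size factors, 0.0665 with the replicate block, 0.0570 without WT 1, 0.128 without WT 2, 0.126 without OX 1, 0.185 without OX 2, 0.0734 without KO 1, 0.0735 without KO 2). The fall was the most abundant member in WT, the flavonoid 3-monooxygenase-like Os08g0547900, from 331 ± 11.7 to 171.2 ± 10.6 CPM (-0.95, SE 0.07, adjusted p = 6.58e-04). Values without a call were Os03g0367101 (1.75, called with plain library totals at adjusted p = 0.0273), Os09g0441700 (0.64), Os04g0581000 (0.30), Os03g0819600 (0.16), Os04g0630800 (0.06) and Os03g0184550 (-1.10, called with DESeq2 size factors at adjusted p = 0.0391).

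**Figure D2:**
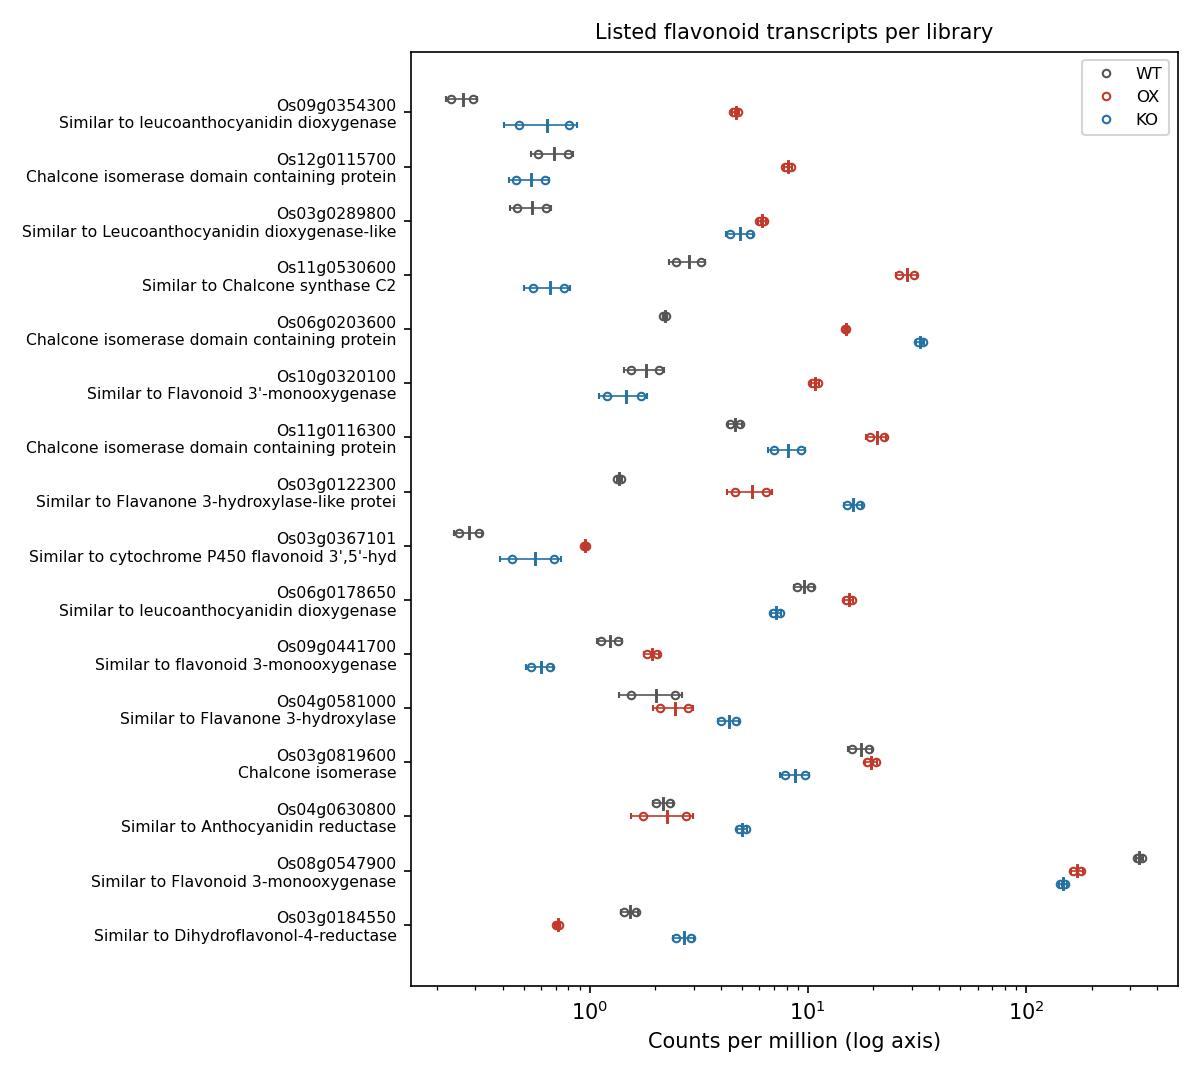
CPM of the 16 listed flavonoid transcripts on a log axis, with circles for single libraries, ticks for group means and bars for SD (n = 2). Chalcone synthase Os11g0530600 stands at 28.5 CPM in OX, 2.85 in WT and 0.658 in KO.

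Phenylpropanoid transcripts, which supply flavonoid and lignin precursors, also rose in OX. Of 27 tested members there were 19 higher and 3 lower. Phenylpropanoid calls adjusted over the list alone were 21 higher and 4 lower. Phenylpropanoid splits were 15 and 3, 19 and 3, and 20 and 3 under the other scalings. The split differed from that of other listed transcripts (Fisher's exact test, two-sided, adjusted p = 0.0249), a call lost with plain library totals (adjusted p = 0.365), with the replicate number as a block (0.264), and on leaving out WT 1 (0.192), WT 2 (0.201), OX 1 (0.205), OX 2 (0.151), KO 1 (0.231) or KO 2 (0.232). Phenylalanine ammonia-lyase, the entry enzyme, rose for Os04g0518400 from 9.57 ± 1.10 to 108 ± 5.51 CPM (log2 fold change 3.50, SE 0.11, adjusted p = 7.97e-05) and for Os02g0627100 from 3.31 ± 0.357 to 36.3 ± 0.464 CPM (3.45, SE 0.13, adjusted p = 1.26e-04). A cinnamyl alcohol dehydrogenase, Os09g0400300, fell from 314 ± 20.6 to 106 ± 3.81 CPM (-1.57, SE 0.06, adjusted p = 1.52e-04).

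Jasmonate transcripts rose in OX, with 16 higher and 1 lower (0 without WT 2, 2 without OX 1, OX 2, KO 1 or KO 2) of 26 tested (direction adjusted p = 0.00914, but 0.172 with DESeq2 calls and 0.0985 without KO 1 or KO 2). Jasmonate calls adjusted over the list alone were 18 higher and 6 lower. Jasmonate splits were 15 and 1, 16 and 1, and 18 and 0 under the other scalings, and 16 and 4 with the DESeq2 Wald test. The Tify-domain gene Os03g0402800, from the family that holds the jasmonate signalling repressors, rose from 51.7 ± 1.23 to 178 ± 3.12 CPM (log2 fold change 1.79, SE 0.05, adjusted p = 6.06e-05). A second lipoxygenase, Os12g0559934, rose as well (4.21, SE 0.19, adjusted p = 2.23e-04), although genes with near-identical sequences may share reads in the authors' counting. Photosynthesis transcripts fell, with 0 higher (1 without KO 1 or KO 2) and 31 lower of 37 tested (adjusted p = 6.70e-11). Photosynthesis calls adjusted over the list alone were 1 higher and 32 lower. Photosynthesis splits were 0 and 32, 0 and 31, and 1 and 30 under the other scalings. The chlorophyll a/b-binding gene Os03g0592500 fell from 14677 ± 551 to 5294 ± 260.5 CPM (-1.47, SE 0.05, adjusted p = 9.06e-05), and the photosystem I gene for PsaO, Os04g0414700, fell from 2842 ± 85.8 to 1099 ± 26.3 CPM (-1.37, SE 0.04, adjusted p = 8.32e-05).

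Drought and late embryogenesis abundant (LEA) transcripts gave 3 higher (1 without OX 2) and 0 lower, of 9 tested in OX. Drought and LEA calls adjusted over the list alone were 3 higher and 0 lower. Drought and LEA splits were 3 and 0, 3 and 0, and 3 and 0 under the other scalings. The title names drought, so this list is not independent evidence of its direction either. The dehydrin Os02g0669100 rose from 57.9 ± 4.29 to 89.0 ± 0.176 CPM (log2 fold change 0.62, SE 0.07, adjusted p = 0.00412). Abscisic acid transcripts gave 7 higher (4 without OX 1 or OX 2) and 1 lower, of 10 tested. Abscisic acid calls adjusted over the list alone were 7 higher and 1 lower. Abscisic acid splits were 6 and 1, 7 and 1, and 7 and 1 under the other scalings. The ABRE-binding factor gene Os02g0766700 rose (1.15, SE 0.07, adjusted p = 4.96e-04). For the protein phosphatase 2C gene Os05g0592800, similar to the abscisic acid signalling repressor ABI2, transcript 02 fell (-1.99, SE 0.26, adjusted p = 0.00727), whereas transcript 03 had a log2 fold change of 1.61 (adjusted p = 0.0365). In the nutrient list there were 10 higher and 2 lower, of 22 tested. Nutrient calls adjusted over the list alone were 12 higher and 3 lower. Nutrient splits were 9 and 2, 10 and 2, and 12 and 2 under the other scalings. Nitrate reductase Os02g0770800 rose from 11.6 ± 0.406 to 189 ± 17.2 CPM (4.02, SE 0.09, adjusted p = 4.50e-05). Heat shock transcripts came to 14 higher and 9 lower, of 46 tested. Heat shock calls adjusted over the list alone were 17 higher and 14 lower. Heat shock splits were 11 and 9, 14 and 9, and 18 and 6 under the other scalings. Redox enzymes came to 17 higher (8 without OX 1, 10 without OX 2) and 10 lower (6 without OX 2), of 65 tested. Redox calls adjusted over the list alone were 24 higher and 15 lower. Redox splits were 13 and 12, 17 and 10, and 25 and 7 under the other scalings. The class III peroxidase Os02g0240300 fell (-2.61, SE 0.10, adjusted p = 1.37e-04). Defence proteins came to 13 higher (8 without WT 2) and 10 lower (6 without WT 2), of 49 tested. Defence calls adjusted over the list alone were 16 higher and 12 lower. Defence splits were 11 and 10, 13 and 10, and 18 and 6 under the other scalings. Chitinase 11, Os03g0132900, rose from 45.5 ± 0.459 to 199 ± 2.80 CPM (2.13, SE 0.05, adjusted p = 4.60e-05). Diterpenoid phytoalexin transcripts came to 1 higher (0 without WT 1, WT 2, OX 1 or OX 2) and 2 lower (1 without WT 1, WT 2, OX 1 or OX 2), of 5 tested. Calls adjusted over the list alone were 1 and 3. The other scalings gave 1 and 2, 1 and 2, and 1 and 1. The replicate block and the DESeq2 Wald test gave 1 and 1. The only clock member matched by description, the ELF3-like Os01g0566050, was not called by edgeR or DESeq2 in any comparison, also adjusted over the list alone, and its unadjusted p in edgeR was not below 0.05 in any of them (log2 fold changes 1.07, 0.90 and 0.17 for OX against WT, KO against WT and OX against KO).

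Marker lists for other cell states were counted beside these groups. In OX against WT, dividing-cell transcripts gave 4 higher (1 without WT 1, WT 2, OX 1 or OX 2) and 7 lower, of 31 tested. Dividing-cell calls adjusted over the list alone were 6 higher and 10 lower. Dividing-cell splits were 4 and 9, 4 and 8, and 4 and 6 under the other scalings. The histone H1 gene Os04g0253000 fell from 753 ± 37.3 to 341 ± 5.83 CPM (log2 fold change -1.14, SE 0.05, adjusted p = 1.95e-04). Meristem transcripts gave 0 higher and 1 lower, of 4 tested. Meristem calls adjusted over the list alone were 0 higher and 3 lower. Meristem splits were 0 and 2, 0 and 1, and 0 and 1 under the other scalings, and 0 and 2 with the DESeq2 Wald test. Secondary wall and vasculature markers gave 0 higher and 1 lower (2 without WT 2), of 4 tested. Secondary wall calls adjusted over the list alone were 0 higher and 2 lower. Secondary wall splits were 0 and 2, 0 and 1, and 0 and 1 under the other scalings, and 0 and 2 with the DESeq2 Wald test. The fall was the sucrose transporter Os03g0170900 (-1.45, SE 0.12, adjusted p = 0.00108). Root markers gave 0 higher and 2 lower (1 without WT 1, WT 2, OX 1, OX 2, KO 1 or KO 2), of 3 tested, and pollen or anther markers gave 3 higher (1 without WT 1, WT 2, OX 1 or OX 2) and 0 lower, of 6 tested. Root calls adjusted over the list alone were 1 higher and 2 lower. Root splits were 0 and 2, 0 and 2, and 0 and 1 under the other scalings, and 0 and 1 with the replicate block. Pollen or anther calls adjusted over the list alone were 3 higher and 0 lower. Pollen or anther splits were 2 and 0, 3 and 0, and 3 and 0 under the other scalings. None of these lists, nor those of the preceding groups other than phenylpropanoid, jasmonate and photosynthesis, differed in direction from the other listed transcripts (adjusted p from 0.215 to 1 over 17 lists tested).

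In total 3099 listed transcripts of 2947 genes differed between OX and WT at an adjusted p below 0.05, 1762 higher and 1337 lower (56.9% higher), and 2611 of them changed at least 2-fold. With plain library totals in place of the authors' scaling the split was 2342 higher and 968 lower (70.8% higher), because that change of scaling shifts every OX to WT log2 ratio by 0.37. With DESeq2 size factors it was 1479 higher and 1536 lower (49.1% higher), which turns the majority. With TMM it was 1723 higher and 1364 lower (55.8% higher). Both were computed on the listed transcripts, which were selected for change, so they do not decide which direction prevails. The number fell to 2013 without OX 1 and 2027 without OX 2. The authors' deposited table calls 3516 transcripts in this comparison at a 2-fold change and an adjusted p below 0.05, 1912 higher and 1604 lower.

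Knockout plants were compared with WT to ask what changes when the MIR171f gene is disrupted. The largest rises included Os12g0264500, similar to the CoA-thioester hydrolase CHY1 (chromosome 12, 9350914 to 9365572), from 0.221 ± 0.0162 CPM in WT to 66.3 ± 4.03 in KO (log2 fold change 8.20, SE 0.46, adjusted p = 6.15e-04). The neighbouring leucine-rich repeat genes Os01g0162300 (chromosome 1, 3256822 to 3257901, 7.67, SE 0.20, adjusted p = 6.38e-05) and Os01g0162200 (chromosome 1, 3251426 to 3252724, 7.004, SE 0.12, adjusted p = 4.38e-05) rose together, their spans being apart but their descriptions alike enough that reads may be shared. The integrin-linked kinase domain gene Os01g0892800, transcript 02, rose from 0.969 ± 0.111 to 116 ± 3.81 CPM (6.90, SE 0.11, adjusted p = 4.38e-05). Abscisic acid 8'-hydroxylase, Os02g0703600, the enzyme that starts abscisic acid breakdown (chromosome 2, 28995717 to 28998452), rose from 21.4 ± 2.896 to 501 ± 1.44 CPM (4.55, SE 0.11, adjusted p = 5.82e-05). The UDP-glucosyltransferase family gene Os07g0489200 fell from 13.3 ± 0.737 to 1.35 ± 0.151 CPM (-3.29, SE 0.20, adjusted p = 5.09e-04), and transcript 02 of the oligopeptidase A gene Os02g0830100 fell from 5.13 ± 0.142 to 0.187 ± 0.00630 CPM (-4.74, SE 0.29, adjusted p = 5.03e-04), while its transcript 03 was not called (2.21). For Os06g0199200 the shift between transcripts seen in OX was present in KO too, with transcript 01 lower (-7.36, SE 0.67, adjusted p = 0.00322), transcript 04 higher (2.32, SE 0.08, adjusted p = 1.02e-04) and 239.8 ± 3.44 CPM in its 3 listed transcripts together.

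Flavonoid transcripts went both ways in KO, with 3 higher, 3 lower and 10 not called among 16, and with 8 higher and 5 lower adjusted over the list alone (direction adjusted p = 0.676). The list is again not independent evidence of its direction. Chalcone isomerase domain gene Os06g0203600 rose from 2.21 ± 0.0478 to 32.8 ± 1.34 CPM (log2 fold change 3.89, SE 0.11, adjusted p = 6.63e-05), as did the flavanone 3-hydroxylase-like Os03g0122300 (3.56, SE 0.23, adjusted p = 6.19e-04), and Os03g0289800, similar to leucoanthocyanidin dioxygenase (3.16, SE 0.27, adjusted p = 0.00159). Chalcone synthase Os11g0530600 fell to 0.658 ± 0.154 CPM (-2.11, SE 0.24, adjusted p = 0.00490) and Os08g0547900 fell to 147 ± 6.02 CPM (-1.17, SE 0.07, adjusted p = 3.82e-04). Chalcone isomerase Os03g0819600 was the remaining fall (-0.998, SE 0.16, adjusted p = 0.0188), with adjusted p 0.0817 without WT 2, 0.102 without KO 2. With other scalings the list gave 3 higher and 5 lower (DESeq2 size factors, and TMM computed on the listed transcripts) or 5 higher and 3 lower (plain library totals, and the DESeq2 Wald test). Phenylpropanoid transcripts gave 13 higher and 3 lower, of 27 tested. Phenylpropanoid calls adjusted over the list alone were 15 higher and 5 lower. Phenylpropanoid splits were 10 and 6, 11 and 5, and 15 and 2 under the other scalings. A 4-coumarate CoA ligase transcript, Os08g0448000, rose from 3.09 ± 0.428 to 17.7 ± 1.55 CPM (2.52, SE 0.18, adjusted p = 9.42e-04).

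Photosynthesis transcripts fell in KO, with 0 higher and 27 lower of 37 tested (Fisher's exact test of direction, two-sided, adjusted p = 1.55e-13). Photosynthesis calls adjusted over the list alone were 0 higher and 31 lower. Photosynthesis splits were 0 and 31, 0 and 30, and 0 and 23 under the other scalings. PsaO, Os04g0414700, fell from 2842 ± 85.8 to 1754 ± 42.0 CPM (log2 fold change -0.70, SE 0.04, adjusted p = 4.86e-04), and the gene for the 22 kDa protein of photosystem II, Os04g0690800, known for its part in dissipating excess light energy, fell from 86.2 ± 7.44 to 34.6 ± 0.925 CPM (-1.31, SE 0.08, adjusted p = 5.80e-04). Jasmonate transcripts gave 15 higher and 1 lower (2 without OX 1, OX 2 or KO 2), of 26 tested (direction adjusted p = 0.166, but 0.00733 with DESeq2 size factors and 0.0135 with TMM on the listed transcripts). Calls adjusted over the list alone were 16 and 2. The other scalings gave 12 and 1, 12 and 1, and 16 and 1, and the DESeq2 Wald test 16 and 2. In this list the Tify-domain genes Os03g0402800 and Os10g0392400 rose, the former from 51.7 ± 1.23 to 388 ± 7.72 CPM (2.91, SE 0.05, adjusted p = 4.38e-05) and the latter from 3.22 ± 0.720 to 48.9 ± 0.1001 CPM (3.93, SE 0.17, adjusted p = 1.75e-04). Heat shock transcripts gave 17 higher and 4 lower (2 without KO 1), of 46 tested (direction adjusted p = 0.676, but 0.0378 with DESeq2 size factors). Calls adjusted over the list alone were 17 and 6. The other scalings gave 16 and 6, 16 and 6, and 17 and 4, and the DESeq2 Wald test 17 and 7. The HSP70 gene Os03g0276500, a protein-folding chaperone, rose from 516 ± 19.9 to 1403 ± 6.47 CPM (1.44, SE 0.04, adjusted p = 6.82e-05). Abscisic acid transcripts gave 5 higher (3 without WT 1, OX 1, OX 2, KO 1 or KO 2) and 1 lower (0 without WT 1, WT 2, KO 1 or KO 2), of 10 tested. Calls adjusted over the list alone were 6 and 3. The other scalings gave 3 and 3, 3 and 2, and 5 and 0, and the replicate block 3 and 0. The osmotic stress kinase gene SAPK2, Os07g0622000, rose in KO (2.18, SE 0.11, adjusted p = 2.41e-04). Drought and LEA transcripts, named in the title and so not independent evidence, gave 2 higher (1 without WT 2, OX 1, OX 2 or KO 2) and 0 lower, of 9 tested. Drought and LEA calls adjusted over the list alone were 8 higher and 1 lower. Drought and LEA splits were 1 and 1, 1 and 1, and 3 and 0 under the other scalings, and 1 and 0 with the replicate block, and 4 and 0 with the DESeq2 Wald test. The dehydrin Os02g0669100 rose (1.35, SE 0.07, adjusted p = 3.19e-04).

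Dividing-cell transcripts in KO gave 5 higher (0 without WT 1, WT 2, KO 1 or KO 2, 2 without OX 1 or OX 2) and 9 lower, of 31 tested. Dividing-cell calls adjusted over the list alone were 8 higher and 10 lower. Dividing-cell splits were 0 and 10, 1 and 10, and 6 and 9 under the other scalings, and 1 and 9 with the replicate block. The linker histone H1 genes Os04g0253000 and Os03g0799000 fell, the former from 753 ± 37.3 to 209 ± 5.17 CPM (log2 fold change -1.85, SE 0.05, adjusted p = 6.38e-05) and the latter from 259 ± 26.0 to 43.7 ± 0.248 CPM (-2.57, SE 0.09, adjusted p = 9.05e-05). The direction of this list was not called (adjusted p = 0.123), but it was called lower with DESeq2 size factors (0.0154), with plain library totals (0.0169) and with the replicate block (0.00121), and without WT 1 (1.19e-04), WT 2 (6.13e-05), OX 1 (0.00625), OX 2 (0.00631), KO 1 (7.03e-05) or KO 2 (7.80e-05).

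Among the other lists, defence proteins in KO gave 16 higher and 4 lower (0 without WT 2, KO 1 or KO 2, 1 without WT 1), of 49 tested. Calls adjusted over the list alone were 20 and 5. The other scalings gave 11 and 7, 13 and 7, and 19 and 3. Os03g0191900, a pathogenesis-related transcriptional factor with an ERF domain, rose from 2.99 ± 0.337 to 43.0 ± 1.34 CPM (log2 fold change 3.85, SE 0.22, adjusted p = 4.13e-04). Redox enzymes gave 15 higher and 4 lower (2 without KO 2), of 65 tested. Calls adjusted over the list alone were 24 and 8. The other scalings gave 10 and 12, 12 and 8, and 17 and 2. The prevailing redox direction turned with DESeq2 size factors. The glutathione S-transferase gene Os04g0435500 rose from 10.9 ± 0.0646 to 62.4 ± 3.67 CPM (2.52, SE 0.08, adjusted p = 9.08e-05). Nutrient transcripts gave 5 higher and 5 lower (1 without KO 1 or KO 2, 2 without WT 1, 3 without WT 2, OX 1 or OX 2), of 22 tested. Calls adjusted over the list alone were 8 and 5. The other scalings gave 4 and 6, 4 and 6, and 6 and 3. Nitrate reductase Os02g0770800 rose (2.85, SE 0.08, adjusted p = 6.75e-05) and the phosphate transporter Os02g0593500 fell (-0.95, SE 0.04, adjusted p = 2.14e-04). Diterpenoid phytoalexin transcripts gave 1 higher and 0 lower, of 5 tested. Calls adjusted over the list alone were 3 and 1. The other scalings gave 1 and 1, 1 and 1, and 2 and 0. The rise was the kaurene synthase A-like Os02g0278700 (1.31, SE 0.15, adjusted p = 0.00477). Meristem markers gave 0 higher and 1 lower (0 without WT 1, WT 2, KO 1 or KO 2), of 4 tested. Calls adjusted over the list alone were 1 and 2. The other scalings each gave 0 and 1, and the replicate block and the DESeq2 Wald test 1 and 1. The call was Os03g0752800, similar to MADS-box transcription factor 14 (-1.33, SE 0.20, adjusted p = 0.0137, with adjusted p 0.0749 without WT 1, 0.0683 without WT 2, 0.0805 without KO 1, 0.102 without KO 2). Secondary wall and vasculature markers gave 1 higher (0 without WT 1, KO 1 or KO 2) and 0 lower, of 4 tested; pollen or anther markers gave 2 higher (1 without WT 2, KO 1 or KO 2) and 0 lower, of 6 tested. Secondary wall calls adjusted over the list alone were 4 higher and 0 lower. Secondary wall splits were 0 and 0, 0 and 0, and 1 and 0 under the other scalings. Pollen or anther calls adjusted over the list alone were 2 higher and 0 lower. Pollen or anther splits were 1 and 0, 2 and 0, and 2 and 0 under the other scalings. Root markers gave no call among 3 tested, over all transcripts or over the list alone, by edgeR's quasi-likelihood test and by DESeq2, 0 of them had an unadjusted p below 0.05, and 1 was called lower with DESeq2 size factors or TMM on the listed transcripts. No list other than photosynthesis differed in direction from the other listed transcripts in KO against WT (adjusted p from 0.123 to 1 over 16 lists tested).

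In total 2534 listed transcripts of 2395 genes differed between KO and WT, 1758 higher and 776 lower (69.4% higher), and 2038 of them changed at least 2-fold. The split depends on the scaling, with 1103 higher and 1356 lower (44.9% higher) under DESeq2 size factors, 1224 higher and 1239 lower (49.7% higher) under TMM computed on the listed transcripts, and 2064 higher and 612 lower (77.1% higher) under plain library totals. The number fell to 1545 without KO 1 and 1577 without KO 2. The authors' deposited table calls 2750 transcripts at a 2-fold change and an adjusted p below 0.05, 1934 higher and 816 lower.

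OX and KO were compared directly because both effects are measured against the same WT libraries, so this contrast tests the difference between them. Chalcone synthase Os11g0530600 was among the transcripts with the largest difference, at 28.5 ± 3.06 CPM in OX and 0.658 ± 0.154 in KO (log2 fold change 5.43, SE 0.26, adjusted p = 2.59e-04). The methyltransferase Os02g0719600 (6.65, SE 0.37, adjusted p = 4.28e-04), the cytochrome P450 gene Os02g0503700, similar to CYP81L6 (5.61, SE 0.35, adjusted p = 6.18e-04), and the sesquiterpene synthase Os08g0167800 (4.71, SE 0.05, adjusted p = 1.92e-05) were also higher in OX. Transcripts lower in OX than in KO included the SP3D-like Os06g0157700 (-5.84, SE 0.31, adjusted p = 4.57e-04), the MADS-domain gene Os03g0215400 (-6.07, SE 0.32, adjusted p = 3.58e-04), the LSD1-type zinc finger gene Os08g0130100 (-6.40, SE 0.27, adjusted p = 1.75e-04) and the abscisic acid 8'-hydroxylase Os02g0703600, at 54.1 ± 2.67 CPM in OX and 501 ± 1.44 in KO (-3.21, SE 0.10, adjusted p = 9.55e-05).

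Among the 16 flavonoid transcripts there were 8 higher (4 without KO 2, 5 without OX 1 or OX 2) and 3 lower in OX against KO (direction adjusted p = 0.0872, but 0.0426 without WT 1, 0.0418 without WT 2 and 0.0425 without KO 1). Flavonoid calls adjusted over the list alone were 9 higher and 4 lower. Flavonoid splits were 9 and 3, 9 and 3, and 9 and 3 under the other scalings. Beside chalcone synthase, the chalcone isomerase domain gene Os12g0115700 stood at 8.13 ± 0.363 CPM in OX and 0.541 ± 0.114 in KO (log2 fold change 3.90, SE 0.30, adjusted p = 0.00110). Flavonoid 3'-monooxygenase Os10g0320100 (2.88, SE 0.28, adjusted p = 0.00260) and leucoanthocyanidin dioxygenase Os09g0354300 (2.86, SE 0.34, adjusted p = 0.00558) were higher in OX, and Os06g0203600 was lower (-1.13, SE 0.10, adjusted p = 0.00172). Phenylpropanoid transcripts gave 12 higher (7 without KO 1) and 5 lower (3 without OX 1), of 27 tested. Phenylpropanoid calls adjusted over the list alone were 13 higher and 7 lower. Phenylpropanoid splits were 12 and 4, 12 and 4, and 12 and 5 under the other scalings. The caffeoyl-CoA O-methyltransferase Os08g0498100, a lignin enzyme, was higher in OX (1.25, SE 0.06, adjusted p = 2.98e-04). That list's direction was called (adjusted p = 0.0287), a call lost with DESeq2 size factors (0.195), TMM on the listed transcripts (0.408), plain library totals (0.107), DESeq2 calls (0.0503), the replicate number as a block (0.0557), and without OX 2 (0.112), KO 1 (0.136) or KO 2 (0.0592).

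Photosynthesis transcripts were lower in OX than in KO, with 2 higher (1 without WT 1, WT 2, OX 1, OX 2 or KO 2) and 27 lower of 37 tested (direction adjusted p = 0.0119, but 0.113 without KO 1 and 0.0592 without KO 2). Photosynthesis calls adjusted over the list alone were 3 higher and 28 lower. Photosynthesis splits were 2 and 17, 2 and 13, and 2 and 25 under the other scalings, and 1 and 27 with the replicate block. The chlorophyll a-b binding gene Os01g0600900, transcript 02, stood at 3112 ± 233 CPM in OX and 7118 ± 36.8 in KO (log2 fold change -1.19, SE 0.08, adjusted p = 6.38e-04). Dividing-cell transcripts gave 9 higher (5 without KO 2) and 3 lower (1 without OX 2, KO 1 or KO 2), of 31 tested (direction adjusted p = 0.0291, but 0.0516 with plain library totals, 0.0503 with DESeq2 calls, 0.0752 without OX 1 and 0.0786 without KO 2). Dividing-cell calls adjusted over the list alone were 14 higher and 4 lower. Dividing-cell splits were 12 and 1, 12 and 1, and 10 and 2 under the other scalings, and 8 and 1 with the replicate block. Histone H1 Os03g0799000 was higher in OX (1.17, SE 0.08, adjusted p = 8.32e-04). Heat shock transcripts gave 2 higher (1 without OX 1, 4 without WT 1 or WT 2) and 17 lower (10 without OX 1, KO 1 or KO 2, 11 without OX 2), of 46 tested. Heat shock calls adjusted over the list alone were 8 higher and 20 lower. Heat shock splits were 6 and 12, 6 and 11, and 3 and 14 under the other scalings, and 4 and 21 with the DESeq2 Wald test. HSP70 Os03g0276500 was lower in OX (-1.04, SE 0.04, adjusted p = 1.61e-04). Jasmonate transcripts gave 5 higher and 8 lower (3 without KO 2, 4 without OX 1 or OX 2, 5 without KO 1), of 26 tested. Jasmonate calls adjusted over the list alone were 5 higher and 12 lower. Jasmonate splits were 7 and 4, 7 and 4, and 5 and 6 under the other scalings. The lipoxygenase Os12g0559200 was higher in OX (4.12, SE 0.18, adjusted p = 3.34e-04).

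Redox enzymes gave 14 higher (5 without KO 2, 6 without OX 1, OX 2 or KO 1) and 17 lower (9 without OX 2, 10 without OX 1 or KO 1, 11 without KO 2), of 65 tested in OX against KO. Redox calls adjusted over the list alone were 16 higher and 26 lower. Redox splits were 16 and 10, 17 and 9, and 15 and 13 under the other scalings. The prevailing redox direction turned with all 3 other scalings. The peroxidase Os02g0240300 was lower in OX (log2 fold change -3.74, SE 0.11, adjusted p = 8.70e-05). Defence proteins gave 11 higher (4 without OX 2 or KO 2, 5 without KO 1, 7 without OX 1) and 16 lower, of 49 tested. Defence calls adjusted over the list alone were 15 higher and 21 lower. Defence splits were 14 and 14, 14 and 14, and 13 and 15 under the other scalings. In the abscisic acid list there were 2 higher (1 without OX 1, OX 2, KO 1 or KO 2) and 3 lower, of 10 tested. Abscisic acid calls adjusted over the list alone were 3 higher and 5 lower. Abscisic acid splits were 2 and 2, 2 and 2, and 2 and 3 under the other scalings, and 1 and 3 with the replicate block. The kinase gene SAPK3, Os10g0564500, was higher in OX (1.23, SE 0.12, adjusted p = 0.00271). Nutrient transcripts gave 6 higher and 6 lower (1 without OX 1, KO 1 or KO 2), of 22 tested. Nutrient calls adjusted over the list alone were 8 higher and 7 lower. Nutrient splits were 9 and 1, 9 and 1, and 8 and 2 under the other scalings. The nitrate transporter-like Os01g0547600 was higher in OX (4.45, SE 0.27, adjusted p = 5.46e-04). Drought and LEA transcripts, again not independent evidence, gave 1 higher (0 without WT 1, WT 2, OX 1, OX 2, KO 1 or KO 2) and 2 lower (1 without WT 1, WT 2, OX 1, OX 2, KO 1 or KO 2), of 9 tested. Drought and LEA calls adjusted over the list alone were 1 higher and 5 lower. Drought and LEA splits were 1 and 1, 1 and 1, and 1 and 1 under the other scalings, and 0 and 1 with the replicate block. Diterpenoid phytoalexin transcripts came to 0 higher and 3 lower, of 5 tested. Diterpenoid phytoalexin calls adjusted over the list alone were 0 higher and 3 lower. Diterpenoid phytoalexin splits were 0 and 2, 0 and 2, and 0 and 2 under the other scalings. Meristem markers came to 0 higher and 1 lower, of 4 tested, secondary wall and vasculature markers to 0 higher and 2 lower (1 without OX 1, OX 2, KO 1 or KO 2), of 4 tested. Meristem calls adjusted over the list alone were 0 higher and 3 lower. Meristem splits were 0 and 1, 0 and 1, and 0 and 1 under the other scalings. Secondary wall calls adjusted over the list alone were 0 higher and 3 lower. Secondary wall splits were 0 and 2, 0 and 2, and 0 and 2 under the other scalings. Root markers came to 0 higher and 1 lower, of 3 tested, and pollen or anther markers to 2 higher (0 without OX 1, OX 2 or KO 1, 1 without KO 2) and 2 lower (0 without OX 1, OX 2, KO 1 or KO 2), of 6 tested. Root calls adjusted over the list alone were 0 higher and 2 lower. Root splits were 0 and 1, 0 and 1, and 0 and 1 under the other scalings. Pollen or anther calls adjusted over the list alone were 3 higher and 2 lower. Pollen or anther splits were 2 and 1, 2 and 1, and 2 and 1 under the other scalings, and 1 and 1 with the replicate block. The lists other than photosynthesis, phenylpropanoid and dividing cells did not differ in direction in OX against KO (adjusted p from 0.0872 to 1 over 17 lists tested).

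In total 2693 listed transcripts of 2565 genes differed between OX and KO, 934 higher and 1759 lower in OX (34.7% higher), and 2091 of them changed at least 2-fold. The split was 1256 higher and 1289 lower (49.4% higher) with DESeq2 size factors, 1350 higher and 1187 lower (53.2% higher) with TMM computed on the listed transcripts, and 1108 higher and 1493 lower (42.6% higher) with plain library totals. The number came to 1584 without OX 1, 1665 without OX 2, 1618 without KO 1 and 1583 without KO 2. The authors' deposited table calls 3004 transcripts at a 2-fold change and an adjusted p below 0.05, 1118 higher and 1886 lower in OX.

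**Figure D3:**
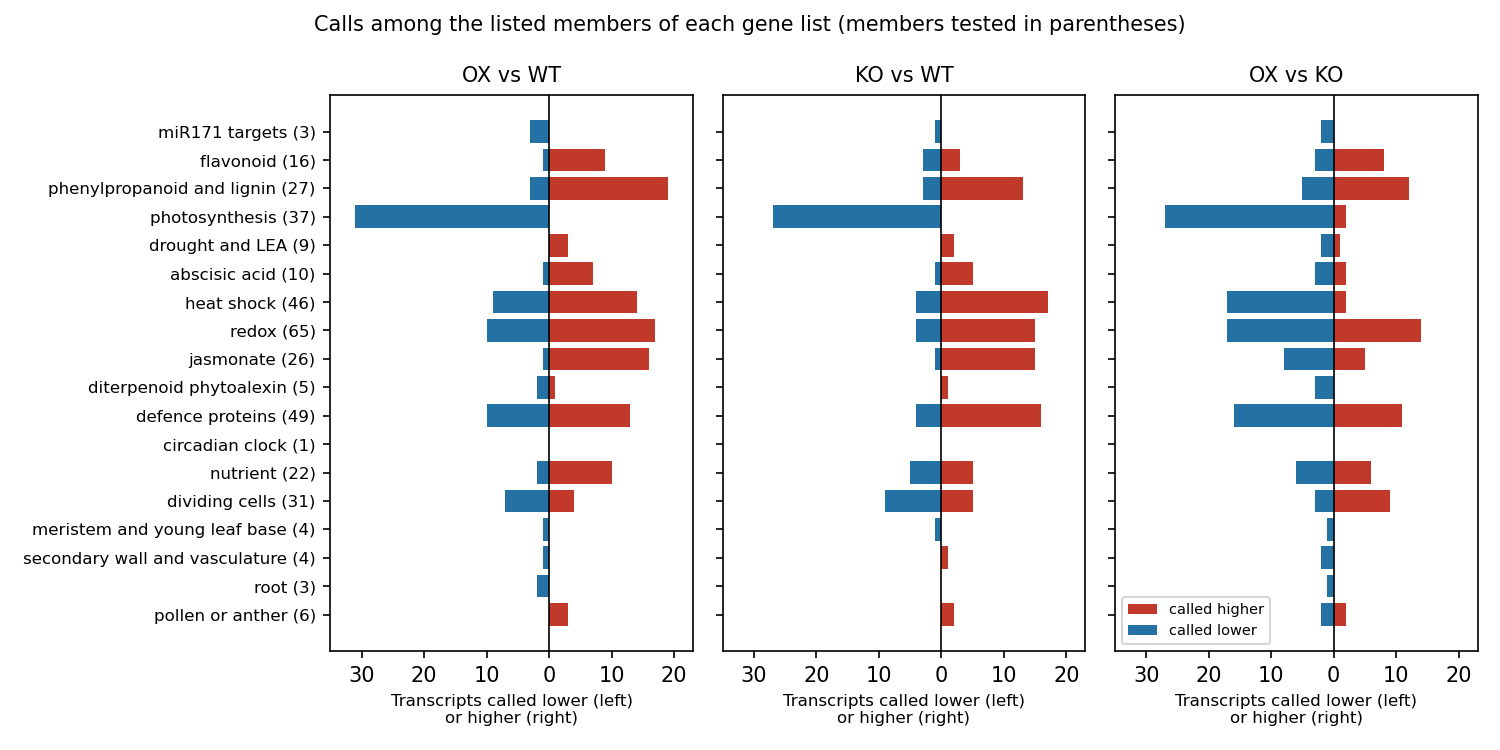
Number of list members called higher (bars to the right) and lower (bars to the left) in each of the 3 comparisons, at an adjusted p below 0.05. Photosynthesis transcripts are called lower 31 times in OX against WT and 27 times in KO against WT, with no member called higher in either (1 in OX against WT with plain library totals, without KO 1 or without KO 2).

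Both genotypes moved many of the same transcripts, and mostly in the same direction. The amino acid transporter Os01g0597600 rose in OX (log2 fold change 3.98, SE 0.08, adjusted p = 3.83e-05) and in KO (4.23, SE 0.08, adjusted p = 4.38e-05), as did the formin-like gene Os02g0739100 (2.54, SE 0.06, adjusted p = 4.50e-05 in OX and 3.55, SE 0.06, adjusted p = 4.38e-05 in KO). In opposite directions, transcript 01 of the LrgB-like gene Os10g0578800 (chromosome 10, 23075402 to 23079074) stood at 64.8 ± 3.09 CPM in WT, 226 ± 5.57 in OX and 18.3 ± 0.300 in KO, and starch synthase I, Os06g0160700, at 142 ± 8.77, 285 ± 9.94 and 68.1 ± 0.175. Of 1710 transcripts called in both comparisons with WT, 1526 (89.2%) moved the same way and 184 opposite ways. Among the 7034 listed transcripts tested, 1017 were higher in both (440.4 for independent lists), 509 lower in both (147.5), 58 higher in OX and lower in KO (194.4), and 126 lower in OX and higher in KO (334.2). Leaving out 1 library lowered the same-direction number to 981 without KO 1 and 1007 without KO 2, and the opposite-direction number to 101 without WT 1, 96 without WT 2, 109 without OX 1, 75 without KO 1 and 73 without KO 2. Over all 27384 transcripts that the authors tested, independent lists would share 113.1, 37.9, 49.9 and 85.8.

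Because both effects are measured against the same WT libraries, unchanged OX and KO groups were simulated against them in 20 draws. The observed covariance of log2 fold changes was 1.204, against a mean of 0.146 and a maximum of 0.160 in the draws, a difference from the mean of 1.06. Pearson's r across transcripts was 0.541 against a simulated mean of 0.510 (maximum 0.536), and 71.5% of transcripts had the same sign against 67.0%. The draws gave a mean of 0.05 transcripts called in both comparisons. Unlike the listed transcripts, the draws were not selected by fold change, a selection that by itself raises the covariance and the share of transcripts called. The 2 WT libraries cannot be split into sets of 2, so part of the excess may come from the shared controls. The balance of shared higher and shared lower calls moved with the scaling, to 1418 and 346 with plain library totals, 633 and 830 with DESeq2 size factors and 772 and 731 with TMM on the listed transcripts.

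**Figure D4:**
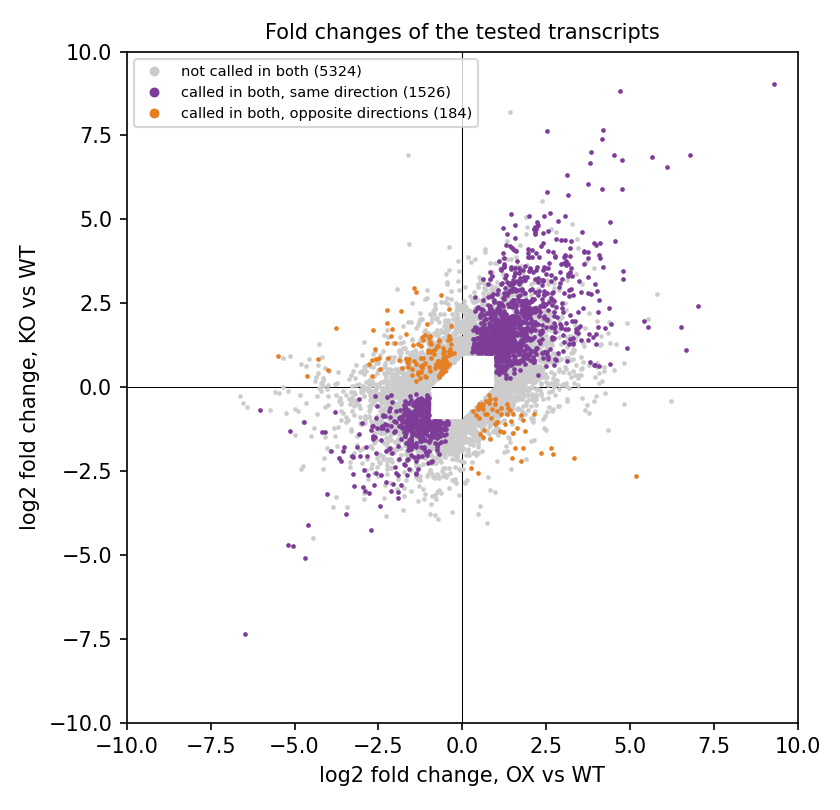
Fold changes of OX against WT (horizontal) and KO against WT (vertical) for the listed transcripts on log2 axes, coloured by whether they are called in both comparisons in the same direction (1526) or in opposite directions (184). The empty centre comes from the authors' selection of transcripts by fold change.

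The authors' deposited table of pathway enrichment places 14 of 36 entries of flavonoid biosynthesis among the 753 selected entries with a pathway, which are listed by transcript ID (false discovery rate 1.02e-10), and 84 of its 124 pathways lie below 0.05. Starch and sucrose metabolism has 44 of 152 entries in the same table (false discovery rate 3.74e-30). In the authors' deposited table of Gene Ontology terms, kinase activity has 498 of 1676 genes (adjusted p = 8.65e-13), flavonoid biosynthetic process has 8 of 19 (adjusted p = 0.415), and 127 of 5820 terms lie below 0.05. Those backgrounds, with 35679 entries for the pathways, were the authors' choice and are not restricted to transcripts that could have passed the selection.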

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

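The tests of chance from the shared WT libraries, of OX and KO set against different WT libraries, of scaling for the flavonoid transcripts and of single OX lines were chosen after the result was seen. In edgeR's direct OX against KO test, all 184 transcripts called in opposite directions against WT differed, which such calls all but ensure. The same test set apart named genes, each given here as log2 fold change of OX against KO with its SE and adjusted p.

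The Scarecrow-like target Os10g0551200 was lower in OX than in KO (-1.16, SE 0.16, adjusted p = 0.00958, adjusted p 0.0670 without KO 1, 0.0603 without KO 2). The target Os02g0662700 was lower in OX as well (-1.06, SE 0.08, adjusted p = 0.00130). Leucoanthocyanidin dioxygenase Os09g0354300 was higher in OX (2.86, SE 0.34, adjusted p = 0.00558). Chalcone isomerase domain gene Os12g0115700 was higher in OX (3.90, SE 0.30, adjusted p = 0.00110). Chalcone synthase Os11g0530600 was higher in OX (5.43, SE 0.26, adjusted p = 2.59e-04). Chalcone isomerase domain gene Os06g0203600 was lower in OX (-1.13, SE 0.10, adjusted p = 0.00172). Flavonoid 3'-monooxygenase Os10g0320100 was higher in OX (2.88, SE 0.28, adjusted p = 0.00260). Chalcone isomerase domain gene Os11g0116300 was higher in OX (1.35, SE 0.18, adjusted p = 0.00942, adjusted p 0.0681 without OX 1, 0.0512 without KO 2). The flavanone 3-hydroxylase-like Os03g0122300 was lower in OX (-1.54, SE 0.21, adjusted p = 0.00892, adjusted p 0.0688 without KO 1).

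The dioxygenase Os06g0178650 was higher in OX than in KO (1.11, SE 0.14, adjusted p = 0.00667, adjusted p 0.0537 without OX 2, 0.0619 without KO 2). Os09g0441700, similar to flavonoid 3-monooxygenase, was higher in OX (1.69, SE 0.30, adjusted p = 0.0232, adjusted p 0.0580 with the replicate block, 0.10 without OX 1, 0.130 without OX 2, 0.136 without KO 1, 0.0940 without KO 2). Chalcone isomerase Os03g0819600 was higher in OX (1.15, SE 0.16, adjusted p = 0.0108, adjusted p 0.0506 without OX 1, 0.0713 without OX 2, 0.0647 without KO 2). Os03g0184550, similar to dihydroflavonol 4-reductase, was lower in OX (-1.92, SE 0.26, adjusted p = 0.00966, adjusted p 0.0749 without OX 1, 0.0769 without OX 2, 0.0612 without KO 2). Among transcripts with opposite signs against WT, the LrgB-like Os10g0578800 (transcript 01) was higher in OX (3.62, SE 0.06, adjusted p = 3.66e-05). Starch synthase I, Os06g0160700, was higher in OX (2.07, SE 0.06, adjusted p = 8.71e-05). The peptidase S41 domain gene Os06g0318600 was higher in OX (1.56, SE 0.05, adjusted p = 8.70e-05). The tetratricopeptide-like gene Os01g0855200 was higher in OX (2.44, SE 0.07, adjusted p = 8.70e-05). The lecithin:cholesterol acyltransferase family gene Os02g0589000 was higher in OX (2.89, SE 0.09, adjusted p = 9.24e-05).

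The first pattern is that OX and KO, which change MIR171f in opposite ways, moved 1526 transcripts from WT in the same direction and 184 in opposite directions. The covariance of the fold changes was 1.204, against a highest simulated value of 0.160. The draws were not selected by fold change as the listed transcripts were, and such selection by itself raises the covariance. Pearson's r (0.541, highest simulated 0.536) and the share with the same sign (71.5%, highest simulated 67.8%) exceeded the draws by less. Chance from the shared WT libraries is therefore not decided by these draws. Without either WT library same-direction calls were at least 11.1 times as many as opposite ones, but the remaining WT library is still shared and gives a high ratio by itself, so this does not decide on a single aberrant WT library. Nor does the overlap under 3 other scalings, at least 2.06 times the number for independent lists, decide on scaling, because lists with shared controls are not independent. With OX and KO libraries set against different WT libraries, so that no library was in common, the covariance of the log2 ratios was at least 1.01, against at most 1.4 with the same WT library, which argues against a single aberrant WT library. With each ratio centred on its median, which removes any scaling of a library, at least 68.2% of the 6254 selected transcripts had the same sign, which argues against scaling as the whole cause. A difference that both transformed genotypes share against nontransgenic plants, such as passage through tissue culture, or a difference in growth or harvest, is a candidate explanation that was not tested, and the genotypes themselves remain open. The labels give no transformed control line, so the design does not separate these.

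The second pattern is that 9 of 16 listed flavonoid transcripts were called higher in OX and 3 in KO. The contrast depends on the threshold, since adjusted over the list alone 10 and 8 were higher, and the direction of the list was called neither against WT (adjusted p = 0.215 in OX, 0.676 in KO) nor in OX against KO (0.0872, but 0.0426 without WT 1, 0.0418 without WT 2 and 0.0425 without KO 1). Scaling of the OX libraries as the whole cause of the rise in OX is argued against by the median log2 fold change of all 16, which was at least 1.7 under each of 4 scalings that differ among themselves by 0.567. A rise in a single OX line is argued against by the median log2 ratio of the 16 to WT, 1.78 in the lower of the 2 OX libraries. Of the 9 called transcripts, 8 stood at least 3.33 times above the highest WT library in both OX libraries, while Os06g0178650 stood 1.44 and 1.54 times above it, alike in both lines but below the 2-fold set for the test. An effect of MIR171f overexpression, passage through tissue culture, and a difference in growth or in the hour of harvest all remain open, and no test here separates these.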

How the results depend on the processing

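The settings with 1 transcript per gene, adjustment over the listed transcripts, the authors' adjusted p and TMM on the listed transcripts were chosen after seeing the data, as were plain library totals for the overlap, lists and named genes and the DESeq2 Wald test for lists. Numbers of transcripts called in OX against WT, KO against WT and OX against KO stayed within 1.5 times of the reported ones under every alternative other than leaving out 1 library: 3555, 2989 and 3215 with the DESeq2 Wald test, 3103, 2532 and 2692 without a filter, 3124, 2542 and 2714 with a minimum of 10 counts, 2695, 2136 and 2600 with only the 2 groups, and 3032, 2470 and 2675 with 1 transcript per gene. Adjusted over the listed transcripts only they were 4386, 3678 and 3977, and by the authors' deposited adjusted p 3970, 3253 and 3690. Leaving out 1 library gave 2013 to 2696 for OX against WT, 1545 to 2158 for KO against WT and 1583 to 2585 for OX against KO, with fewer libraries to estimate the spread from.

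Transcripts called in both comparisons with WT numbered 945 at an adjusted p below 0.01, and 1056 to 1240 with 1 library left out. Lists with a called direction in OX against WT numbered 3, and 1 to 2 with 1 library left out. In KO against WT they numbered 1, but 4 with DESeq2 size factors, 2 with plain library totals, 2 with TMM on the listed transcripts and 2 without any 1 library. In OX against KO they numbered 3, but 1 with plain library totals, 1 with the DESeq2 Wald test and 0 to 4 with 1 library left out. The cause was not tested beyond the loss of libraries.

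The replicate numbers of the labels did not pair the libraries: deviations from group means of same-numbered libraries correlated at 0.076, 0.023 and 0.016. With the number as a block, 2695, 2158 and 2308 transcripts were called, 1440 in both comparisons with WT, and 2 lists had a called direction in each comparison.

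Of 317 fold changes of named transcripts none changed sign where called. The call was the same for 308 with the DESeq2 Wald test, 299 with DESeq2 size factors, 305 with TMM on the listed transcripts, 305 with plain library totals, 301 with the replicate block and 289 to 302 with 1 library left out. The estimated correlation planned for a set test was not run, because no set test was made, and the pseudocount did not apply to counts. OX against WT data were simulated at this depth and each transcript's estimated dispersion, with 2 libraries per group. In them 7.67% of 2-fold rises and 5.67% of 2-fold falls were called. The limits set by depth and by the number of libraries were not separated.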

Other observations

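The tests of neighbouring genes, of starch synthesis and of a single OX line were chosen after the result was seen, as were the genes of the starch and transcript comparisons. Transcripts for starch-synthesis enzymes were a group outside the fixed lists. Of 12 listed transcripts, 9 rose in OX and 1 fell, a count of higher calls between 8 and 9 over all scalings, the DESeq2 Wald test and the removal of any 1 library. Beside the ADP-glucose pyrophosphorylase Os05g0580000 (log2 fold change 7.02, SE 0.17, adjusted p = 6.06e-05), the rises included the debranching enzyme ISO3, Os09g0469400 (2.57, SE 0.07, adjusted p = 6.06e-05), branching enzyme I, Os06g0726400, transcript 01 (2.02, SE 0.25, adjusted p = 0.00851, adjusted p 0.0765 without WT 1, 0.0731 without WT 2), and starch synthase I, Os06g0160700 (1.004, SE 0.06, adjusted p = 4.52e-04). In KO 3 rose and 3 fell (2 and 6 with DESeq2 size factors or TMM on the listed transcripts, 2 and 2 without WT 1, WT 2 or KO 1, 3 and 2 without OX 1, OX 2 or KO 2). The KO rises were Os05g0580000 (2.42, SE 0.15, adjusted p = 6.38e-04), the pyrophosphorylase Os01g0633100 (1.04, SE 0.09, adjusted p = 0.00178) and starch synthase V, Os02g0807100, transcript 01 (0.68, SE 0.10, adjusted p = 0.0142, adjusted p 0.714 with DESeq2 size factors, 0.281 with TMM on the listed transcripts, 0.0670 without WT 1, 0.0558 without WT 2, 0.0948 without KO 1). Starch synthase I fell in KO (-1.06, SE 0.06, adjusted p = 4.27e-04), as did granule-bound starch synthase Ib, Os07g0412100 (-0.65, SE 0.05, adjusted p = 8.65e-04), which rose in OX (0.48, SE 0.05, adjusted p = 0.00226), and isoamylase Os08g0520900 (-0.9999, SE 0.17, adjusted p = 0.0206, adjusted p 0.0570 without WT 1, 0.0859 without WT 2, 0.0622 without OX 1, 0.0673 without OX 2, 0.107 without KO 1, 0.119 without KO 2). The hypothesis that starch transcripts rose in OX beyond the split of the other listed transcripts (1753 higher, 1336 lower) missed the threshold (Fisher's exact test, two-sided, p = 0.0506), so it is neither upheld nor excluded.

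Transcripts of 1 gene could move apart in both genotypes. Among 551 genes with several tested transcripts, 17 had transcripts called in opposite directions in OX against WT (27 with the DESeq2 Wald test, 9 without OX 1 and 9 without OX 2) and 10 in KO against WT (16 with the DESeq2 Wald test, 6 without KO 2), and 6 genes did so in both. The ADP-ribosylation factor-like gene Os11g0586900 had transcript 02 higher (3.74 in OX and 3.86 in KO) and transcript 01 lower (-1.04 and -1.05). In Os01g0800300 transcript 01 was higher (3.62 and 3.68) and transcript 03 lower (-5.19 and -4.71), while both together held 8.78 ± 2.34 CPM in WT, 10.7 ± 0.506 in OX and 11.2 ± 0.0195 in KO.

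The third pattern is the fall of florigen and floral MADS transcripts in OX, where all 4 listed of 11 flowering genes written by ID were called lower, also with each library left out: Os06g0157700 (-6.42), Os03g0752800 (-4.09), Os07g0605200, MADS box transcription factor 18 (-1.53), and Os03g0215400 (-6.53). Part of the fall is shared with KO, where Os03g0752800 (-1.33, SE 0.20, adjusted p = 0.0137, adjusted p 0.0749 without WT 1, 0.0683 without WT 2, 0.0805 without KO 1, 0.102 without KO 2) and Os07g0605200 (-0.84, SE 0.06, adjusted p = 6.81e-04) were lower than in WT, and all 4 were called lower in OX than in KO. Each OX library lay at least 2.83 times below the lowest WT library for all 4. Calls with 2 libraries need both to be low, so this does not test for a single OX line. Sampling at another time of day remains open: of 10 clock genes written by ID 4 were listed, and 4 were called higher in OX (2 with DESeq2 size factors, 2 without WT 1, 2 without WT 2, 2 without OX 1 and 1 without OX 2), so a different harvest hour may contribute. A slower change to flowering in OX also remains open, since among the flowering genes not seen before only 1, Os07g0605200, was called.

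Neighbouring genes changed together more often than in shuffled positions. In OX against WT, 15 of 2678 pairs of listed genes within 20 kb were both called with at least an 8-fold change in the same direction, against a mean of 2.25 and a highest value of 8 in 1000 shuffles. In KO against WT there were 17 pairs (shuffled mean 2.35, highest 8), among them Os01g0162200 and Os01g0162300, with log2 fold changes of 7.004 and 7.67. Identical descriptions that name a function or family account for 1 of the pairs in OX and 5 in KO, and similar genes, like overlapping ones, may share reads, so the hypothesis of joint local change fits these counts but is not separated from shared reads.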
